A study of Mus musculus with 6 samples.

How the data were processed

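The samples were 6 arrays of Thy1.2+ cells, magnetically purified from E17.5 Rag1-/- mouse fetal thymi: 2 from fresh thymi (0 h), 2 from thymi kept for 40 h with anti-CD3 and DMSO, and 2 from thymi kept for 40 h with anti-CD3 and 50 µM 79-6. That whole thymi were cultured is taken from the series design; the sample labels do not mention organ culture. Per the labels, RNA was extracted with the PicoPure kit, labelled with biotin and hybridised to a 1-colour Affymetrix whole-transcript array. The submitters' processing notes name RMA and the R package oligo, whose versions are not given in the sources used here. The deposited values are RMA intensity values, on the linear scale: they run from 8.75 to 25316, and their log2 from 3.13 to 14.63. The planned tests assumed log2 values, so log2 was taken before every test. Arrays give no counts, detection p-values were not used here, and precision rests on 2 arrays per group.

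The table held 34760 probe sets. The annotation gave a single gene symbol to 21640, several symbols to 1321 and none to 11799. Genes were named through these symbols, and matching Entrez identifiers to a list of RefSeq genes (21553 matched) changed 0 of them. No coordinates were used, since no genome build is named in the sources used here. For each of 19937 genes the probe set with the highest mean over the 6 arrays was tested; 954 genes had more than 1. Identifiers of the probe sets behind main results are 10438738 for Bcl6, 10533182 for Dtx1, 10469278 for Il2ra, 10538993 for Cd8a, 10410007 for Fbp1, 10585749 for Cyp1a1, 10430186 for Apol7c, 10497451 for Cpa3, 10567034 for Pth, 10485372 for Rag1 and 10584628 for Thy1. No missing values were present and no array was left out.

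The 3 comparisons were DMSO against fresh, 79-6 against DMSO and 79-6 against fresh. All 6 arrays were fitted together with 1 mean per group (limma 3.58.1 in R 4.3.3, lmFit and eBayes without trend or robust settings; 3 residual and 4.24 prior degrees of freedom), two-sided, with Benjamini-Hochberg adjustment over 19937 genes and a threshold of 0.05. Errors are limma standard errors (SE) for changes and standard deviations (SD) for group means. Whether replicate numbers pair arrays across groups is not known. Deviations of same-numbered arrays from their group means correlated at 0.0036, 0.0948 and -0.0740 across genes, which does not settle it. The main fit was planned without a block, and a replicate block was run as an alternative. Splits of the arrays into other groups were not counted, because groups hold 2 arrays.

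Gene lists were tested with camera (limma) at a preset inter-gene correlation of 0.01, two-sided, with adjustment over the 30 lists of a comparison. Camera with a correlation estimated per list and camera on ranks were run beside it. So was fry, which tests whether a list's genes move one way without comparing them with other genes. With an estimated correlation camera uses the 3 residual degrees of freedom, and with the preset one nearly as many as there are genes. Its p with an estimated correlation is therefore larger even where that correlation is low. The lists were the Notch pathway, DN3 and earlier progenitor genes, beta-selection and DP genes, T-lineage transcription factors, T cell receptor signalling, activation-induced genes, candidate Bcl6 targets, S phase, G2 and mitosis, p53 targets, apoptosis regulators, Nrf2, ATF4 and unfolded protein response, heat shock, AhR and xenobiotic genes, glycolysis and hypoxia, cholesterol synthesis, ribosome biogenesis and Myc targets, interferon-stimulated genes, cytokines and receptors, homing receptors, and markers of NK and innate-lymphoid cells, macrophages and dendritic cells, granulocytes and mast cells, B cells, erythroid cells, thymic epithelium, mesenchyme and endothelium, platelets, and general T-lineage and leukocyte genes. Of 572 entries 516 were measured. Lists overlap, with 9 Notch, 8 DN3, 8 DP, 9 transcription factor, 11 Bcl6 candidate, 5 activation, 5 cytokine, 4 homing, 4 NK and 8 general members also in another list. The NK list includes genes that T-lineage cells express too, such as Id2, Il2rb and Gzmb.

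Named genes were, per comparison, the 12 with the largest change in each direction among genes past the threshold whose arrays did not overlap between groups, then Bcl6, Rag1 and Thy1, and from each list the 2 to 4 called members with the largest change; for a list without calls, up to 3 members with the smallest p; and any member of the Notch, transcription factor and Bcl6 candidate lists. Comparisons, tests, lists, this rule and all alternatives but the covariate below were chosen before the data were examined. Members named outside the rule were chosen after their values were seen: Cd28, Cd3d, Cd3e, Cd6, Dntt, Fosb, Foxn1, Gzma, Ltb and Mycn for DMSO against fresh, and Ahr, Cd4, Cd8a, Cd8b1, Gzma, Lyz2 and Rag2 for 79-6 against DMSO, as were the genes that illustrate both responses together.

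The alternatives were the replicate block, trend and robust settings, a fit of only the groups compared, leaving out the dimmest 30% of genes, quantile normalisation again, arrays set to 1 median, the mean of a gene's probe sets, every probe set tested, a fold of at least 2, and leaving out each array in turn. A fit that leaves 1 array in a group assumes that this array varies like the other groups. Where a comparison does not use that group, leaving out either of its arrays gives the same fit as the compared groups alone. The 6 fits of a comparison that each leave out 1 array are therefore not all distinct. Each array's median over macrophage and dendritic cell markers was added as a covariate after the data were seen. For the correlation between responses, unchanged groups sharing the DMSO arrays were simulated 200 times.

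The test of 79-6 against DMSO was tested on simulated data with 200 changed genes in each of 10 runs: it recovered 38.7% of log2 changes of 0.5, 94.5% of changes of 1 and 99.9% of changes of 2, and 5.4% of its calls were false. Camera called 10 of 10 shifted lists and 0 of 290 others. The simulated genes varied independently of one another. This therefore does not test camera on lists of correlated genes, such as the macrophage list (estimated correlation 0.71). Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9. Raw array files were not used here.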

Results

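Gene expression was measured on 6 one-colour whole-transcript mouse arrays from Thy1.2+ thymocytes of E17.5 Rag1-/- fetal thymi. Without Rag1 the T cell receptor genes are not rearranged, so thymocytes stop at the double-negative 3 (DN3) stage, and antibody to CD3 replaces the missing pre-T cell receptor signal. There were 3 groups of 2 arrays: fresh cells at 0 h, cells from thymi stimulated with anti-CD3 for 40 h in DMSO, and cells from thymi stimulated for 40 h with 50 µM 79-6, an inhibitor of the BTB domain of the transcriptional repressor Bcl6. Replicates are called by their group and number. The median intensity of an array lay between 99.3 and 103.6, and arrays give no depth in counts, so their number limits the precision. Replicate arrays correlated at 0.998 (fresh), 0.998 (DMSO) and 0.997 (79-6) across genes, against 0.979 to 0.995 between groups. The first principal component held 68.9% of the variance and the second 17.3%. The labels do not say that replicates are separate cultures or litters, so p-values measure only the spread between arrays.

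The first comparison, DMSO at 40 h against fresh cells, asks what 40 h of culture with anti-CD3 changed before any inhibitor is considered. Coreceptor genes of the DP stage rose, Cd8a more than any other gene. It went from 7.81 ± 0.05 (SD, n = 2) to 12.17 ± 0.04 (SD, n = 2) on the log2 scale, a 20.5-fold rise with an adjusted p of 4.6e-07 (limma), Cd4 rose 9.41-fold and Cd8b1 8.41-fold. Fbp1, a gluconeogenic enzyme, fell furthest, from 11.96 ± 0.02 to 6.51 ± 0.03 (43.6-fold, adjusted p = 2.2e-07 by limma). Bcl6 itself rose by a log2 change of 1.64 ± 0.09 (SE, adjusted p = 5.1e-05). The group was cultured and stimulated and the fresh one was neither, so this comparison holds culture, time, vehicle and anti-CD3 together.

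After Cd8a the largest rises with DMSO were in the myeloid genes Mmp8 (log2 change 4.03) and Lyz2 (3.88). Ly6a2 (3.60), the adhesion receptor Cd2 (3.35) and Gm9733 (3.24) came before the other coreceptor genes, and Ifitm6 (3.02), Hp (2.90), the GTPase gene Gimap3 (2.89) and the transcription factor Ikzf3 (2.81) after them. The largest falls after Fbp1 were in Khdc1a (-5.06), Mpzl2 (-3.51), Cdh23 (-3.26), Scin (-3.24), B4galnt2 (-3.20), Myl10 (-3.07), Vwce (-2.90), Capn5 (-2.75), the heme synthesis gene Alas2 (-2.73), Uaca (-2.66) and Myl4 (-2.59). Adjusted p-values of these genes lay between 5.6e-06 and 0.0018 by limma. Thy1, the antigen used for purification, rose by 0.43 (adjusted p = 0.0053). Rag1 signal fell by 0.34 (adjusted p = 0.0152), a call lost without fresh replicate 1 (0.109), DMSO replicate 1 (0.0575) or DMSO replicate 2 (0.0872). Where the Rag1 probes lie relative to the deletion is not known here, so this signal does not check the genotype. Probe sets of gene families such as Ly6, Gimap and Khdc1 can also read related genes.

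Genes of the Notch pathway and of the DN3 stage fell and genes of the double-positive (DP) stage rose. In the Notch list 10 of 18 measured members fell and 1 rose (10 and 2 adjusted over the list alone). The falls included Il2ra (-1.94), Ptcra (-1.86), Hes1 (-1.52), Dtx1 (-1.52), Notch3 (-1.46), Hey1 (-1.43), Nrarp (-1.32), Heyl (-1.28) and Notch1 (-0.92), while Ikzf1 rose by 0.73. The list median was -0.78 (camera, adjusted p = 1.5e-05 and adjusted p = 0.233 with an estimated correlation). Of 20 genes of DN3 and earlier progenitors, 14 fell and 2 rose (14 and 4 adjusted over the list alone). Their median was -0.98 (camera, adjusted p = 2.7e-09 and adjusted p = 0.196 with an estimated correlation). Among them were the progenitor transcription factor Erg (-2.38), the stem cell factor receptor Kit (-1.65) and Mycn (-1.53), and Dntt, the terminal transferase, rose by 0.99. Without fresh replicate 1 or either DMSO array 1 rise was called, that of Dntt. In the list of beta-selection and DP genes 15 of 22 rose and 5 fell (15 and 7 adjusted over the list alone). Cd6 (2.66), Ccr9 (2.42), Cd28 (2.30) and Cd5 (2.23) followed Cd2 and the coreceptors, whereas Cd3g (-0.68), Cd3d (-0.47) and Cd3e (-0.47), which encode chains of the CD3 complex, fell. Its median was 0.65 (camera, adjusted p = 5.7e-06 and adjusted p = 0.249 with an estimated correlation).

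T-lineage transcription factors split, with 10 of 20 higher and 4 lower in DMSO (10 and 4 adjusted over the list alone, median 0.26). Id3, a target of pre-T cell receptor signals, rose by 2.46 and the chromatin organiser Satb1 by 1.23, and Runx1 (-1.20), Id2 (-0.58) and Myb (-0.45) fell. Camera called this list (adjusted p = 0.0233 and adjusted p = 0.610 with an estimated correlation), but not on ranks (0.206). The list of T cell receptor signalling components was not called (6 higher, 5 lower of 17, with 7 and 5 adjusted over the list alone, median 0.17, adjusted p = 0.162), although Rasgrp1 (1.58) and Zap70 (1.42) rose and the ubiquitin ligase gene Cblb fell by 1.87. Without either fresh array or DMSO replicate 1, 3 falls were called. Activation-induced genes divided evenly, 6 higher and 6 lower of 22 (7 and 7 adjusted over the list alone, median 0.02, adjusted p = 0.642): Nr4a1 rose by 1.19 while Jun (-1.28) and Fosb (-1.09) fell. Without fresh replicate 2 or DMSO replicate 1 the lower members numbered 3. Of 21 candidate targets of Bcl6, a list that includes Bcl6, 5 rose and 9 fell (6 and 10 adjusted over the list alone, median -0.19, adjusted p = 0.170). S1pr1, a receptor for thymic exit, rose by 2.27 with its activator Klf2 (1.01), and Gpr183 (-2.31), Socs2 (-2.15) and the cyclin Ccnd2 (-1.01) fell. The general T-lineage and leukocyte list had 8 of 13 higher and 3 lower (8 and 3 adjusted over the list alone) and a median of 0.43 (adjusted p = 0.0430 and adjusted p = 0.534 with an estimated correlation). That call was lost without DMSO replicate 2 (0.0623) or either 79-6 array (0.0651), and on ranks (0.0811).

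All 21 measured genes of G2 and mitosis were higher in DMSO than in fresh cells (21 adjusted over the list alone), among them the mitotic genes Bub1 (1.09), Hmmr (1.09) and Cenpf (0.97). The median was 0.68 (camera, adjusted p = 7.9e-17 and adjusted p = 0.291 with an estimated correlation). S phase and replication genes were not called as a list (7 higher and 1 lower of 23, with 8 and 2 adjusted over the list alone, median 0.03, adjusted p = 0.170). Rrm2 rose by 0.87 and the cyclins Ccne1 and Ccne2 by 0.84 and 0.69. The higher S phase members numbered 3 without fresh replicate 1 or DMSO replicate 1 and 4 without the other fresh or DMSO array, and none was lower in these 4 fits. Glycolysis and hypoxia genes rose in 10 of 19 cases with none lower (11 adjusted over the list alone), led by the phosphofructokinase Pfkp (1.46), Egln3 (1.29), Bnip3 (1.17) and P4ha1 (0.98). Their median was 0.36 (camera, adjusted p = 3.2e-06 and adjusted p = 0.610 with an estimated correlation), and 5 were called without fresh replicate 1 or DMSO replicate 2. Ribosome biogenesis and Myc target genes fell, 13 of 20 with none higher (17 lower adjusted over the list alone), including Mybbp1a (-0.65), Myc (-0.63) and Polr1b (-0.54). The median was -0.39 (camera, adjusted p = 9.5e-09 and adjusted p = 0.423 with an estimated correlation), with 8 called without fresh replicate 1 and 7 without DMSO replicate 2. Cholesterol synthesis genes were lower in 5 of 16 cases (5 adjusted over the list alone, median -0.13, adjusted p = 0.0180 and adjusted p = 0.667 with an estimated correlation). None of these 5 was called without DMSO replicate 1, 1 without fresh replicate 1 or DMSO replicate 2, and the list call was lost without fresh replicate 1 (0.0974) or DMSO replicate 1 (0.0539).

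Interferon-stimulated genes fell in 15 of 17 cases with none higher (16 adjusted over the list alone), with Oasl2 (-1.97), Ifit1 (-1.75), Cxcl10 (-1.69) and Rsad2 (-1.63) furthest down. The median was -1.31 (camera, adjusted p = 4.8e-16 and adjusted p = 0.249 with an estimated correlation). Cytokines and their receptors were not called as a list (4 higher, 7 lower of 21, with 4 and 7 adjusted over the list alone, median -0.16, adjusted p = 0.162): Ifng fell by 1.13, and Il6ra (1.38) and Ltb (0.92) rose. It was called without fresh replicate 1 (0.0128). Chemokine, integrin and homing receptors were not called either (7 higher, 3 lower of 19, with 9 and 3 adjusted over the list alone, adjusted p = 0.170); Itgb2 (1.67) and Itgb7 (1.03) rose. Here the median was -0.10 while the mean was 0.43 and camera's direction was up, the list was called without fresh replicate 2 (0.0115), and no member was called lower without that array or either DMSO array.

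In the main test camera did not call the stress and survival lists from fresh to DMSO. Fry called p53 targets (adjusted p = 0.0367) and apoptosis regulators (0.0056) higher. It called Nrf2 (0.0367), ATF4 (0.0020) and heat shock genes (0.0221) lower, but not the AhR list (0.188). Among p53 targets 6 of 18 rose and 3 fell (9 and 3 adjusted over the list alone, median 0.22, adjusted p = 0.0572), with the death receptor Fas up by 1.55. The list was called without fresh replicate 2 (0.0460) or DMSO replicate 1 (0.00990), and 3 rises were called without either fresh array or DMSO replicate 2. Of 15 apoptosis regulators 3 rose and 2 fell (4 and 2 adjusted over the list alone, median 0.14, adjusted p = 0.162): the anti-apoptotic gene Bcl2l1 rose by 1.12 and its relative Bcl2 fell by 0.70. Nrf2 oxidative stress genes (2 higher, 4 lower of 19, with 2 and 8 adjusted over the list alone, median -0.11, adjusted p = 0.162) included Slc7a11 (1.38) and Gsr (-0.77), with 2 lower without fresh replicate 2 or either DMSO array. ATF4 and unfolded protein response genes (2 higher, 5 lower of 21, with 5 and 5 adjusted over the list alone, median -0.02, adjusted p = 0.636) included Atf3 (1.16) and Slc7a5 (-0.50), with 3 lower without either fresh array or DMSO replicate 2 and 1 higher without fresh replicate 1 or DMSO replicate 2. Heat shock genes (1 higher, 1 lower of 13, with 1 and 1 adjusted over the list alone, median -0.11, adjusted p = 0.162) included Hspb1 (-1.18) and Dnajb1 (0.41), with 2 lower without DMSO replicate 2. In the aryl hydrocarbon receptor (AhR) and xenobiotic list 1 of 10 members rose, Tiparp (0.58), and 2 fell, Ahr (-1.61) and Nqo1 (-1.34), with the same counts adjusted over the list alone, a median of -0.00 and an adjusted p of 0.752.

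Markers of other cell types also moved. The series design names organ cultures of fetal thymi as the stimulated material, whereas the sample labels speak only of stimulation, so whether these cell types were present during the 40 h rests on the former. Thymic epithelial markers fell in 14 of 16 cases with none higher (14 adjusted over the list alone), among them Cdh1 (-2.34), Tbata (-1.66), Krt5 (-1.57), Pax1 (-1.50) and Foxn1 (-1.28). Their median was -1.23 (camera, adjusted p = 2.1e-10 and adjusted p = 0.249 with an estimated correlation). Macrophage and dendritic cell markers rose in 8 of 20 cases with none lower (11 adjusted over the list alone), led by Lyz2, Adgre1 (1.63), Itgam (1.55) and Csf1r (1.43). Their median was 0.56 (camera, adjusted p = 3.0e-05 and adjusted p = 0.620 with an estimated correlation), but the fresh arrays themselves stood at -0.34 and 0.34 around their mean. The 8 became 12 without fresh replicate 2, 5 without DMSO replicate 1 and 4 without DMSO replicate 2. Granulocyte and mast cell markers rose in 6 of 15 cases and 1 fell (6 and 2 adjusted over the list alone, median 0.26, adjusted p = 0.0180 and adjusted p = 0.620 with an estimated correlation): S100a8 (2.03), Elane (1.49) and S100a9 (1.25) against the mast cell protease Cpa3 (-1.61). Cytotoxic, natural killer (NK) and innate-lymphoid markers fell in 9 of 17 cases and rose in 3 (9 and 3 adjusted over the list alone), with Gzmb (-2.28), Xcl1 (-1.42) and Nkg7 (-1.28) down and Gzma up 2.01-fold. The median was -0.43 (camera, adjusted p = 0.0158 and adjusted p = 0.667 with an estimated correlation); the call was lost without fresh replicate 2 (0.157), and 1 rise was called without either DMSO array.

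The remaining marker lists were not called from fresh to DMSO. B cell markers had 0 higher and 2 lower of 12, Ebf1 (-1.12) and Blk (-0.81); the median was 0.01, the mean -0.12 and camera's direction down (adjusted p = 0.642). Erythroid markers had 2 higher, Hemgn (0.60) among them, and 3 lower of 9, led by Alas2. There was 1 higher without either fresh array or DMSO replicate 1, and 1 lower without fresh replicate 2 or DMSO replicate 1. Their median was 0.02 against a mean of -0.29 and a downward camera direction (adjusted p = 0.821). Mesenchymal and endothelial markers had 1 higher and 4 lower of 15, with Pdgfrb (-1.60) lowest, 2 lower without DMSO replicate 1, none higher without either fresh array or DMSO replicate 2, and a median of -0.02 (adjusted p = 0.162; 0.0128 without fresh replicate 1 and 0.0426 without DMSO replicate 2). Platelet markers had 1 higher of 7, Itgb3 (0.69), and a median of -0.03 (adjusted p = 0.878), with 2 higher without fresh replicate 2 and 1 lower without fresh replicate 1. Adjusted over the list alone the higher and lower counts were 0 and 2 for B cell, 2 and 3 for erythroid, 2 and 4 for mesenchymal and 1 and 1 for platelet markers.

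In this comparison limma called 3902 of 19937 genes at an adjusted p under 0.05, 1773 higher and 2129 lower in DMSO, of which 519 differed at least 2-fold. With arrays set to 1 median it was 2155 higher and 1822 lower, so the larger direction depends on the scaling. The count was 2286 without fresh replicate 1, 2382 without fresh replicate 2, 2292 without DMSO replicate 1 and 2347 without DMSO replicate 2, each leaving 1 array in a group. With the macrophage marker median of each array as a covariate, chosen after the data were seen, it was 1434. Camera called 14 of 30 lists, 7 up and 7 down, and fry called 19, with 10 called by both. With an estimated correlation camera called 0, where 5 had an unadjusted p under 0.05 and the lowest adjusted p was 0.196. Of 272 list members and rule-named genes called here, 196 kept the call in each of the 6 fits that left out 1 array.

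**Figure D1:**
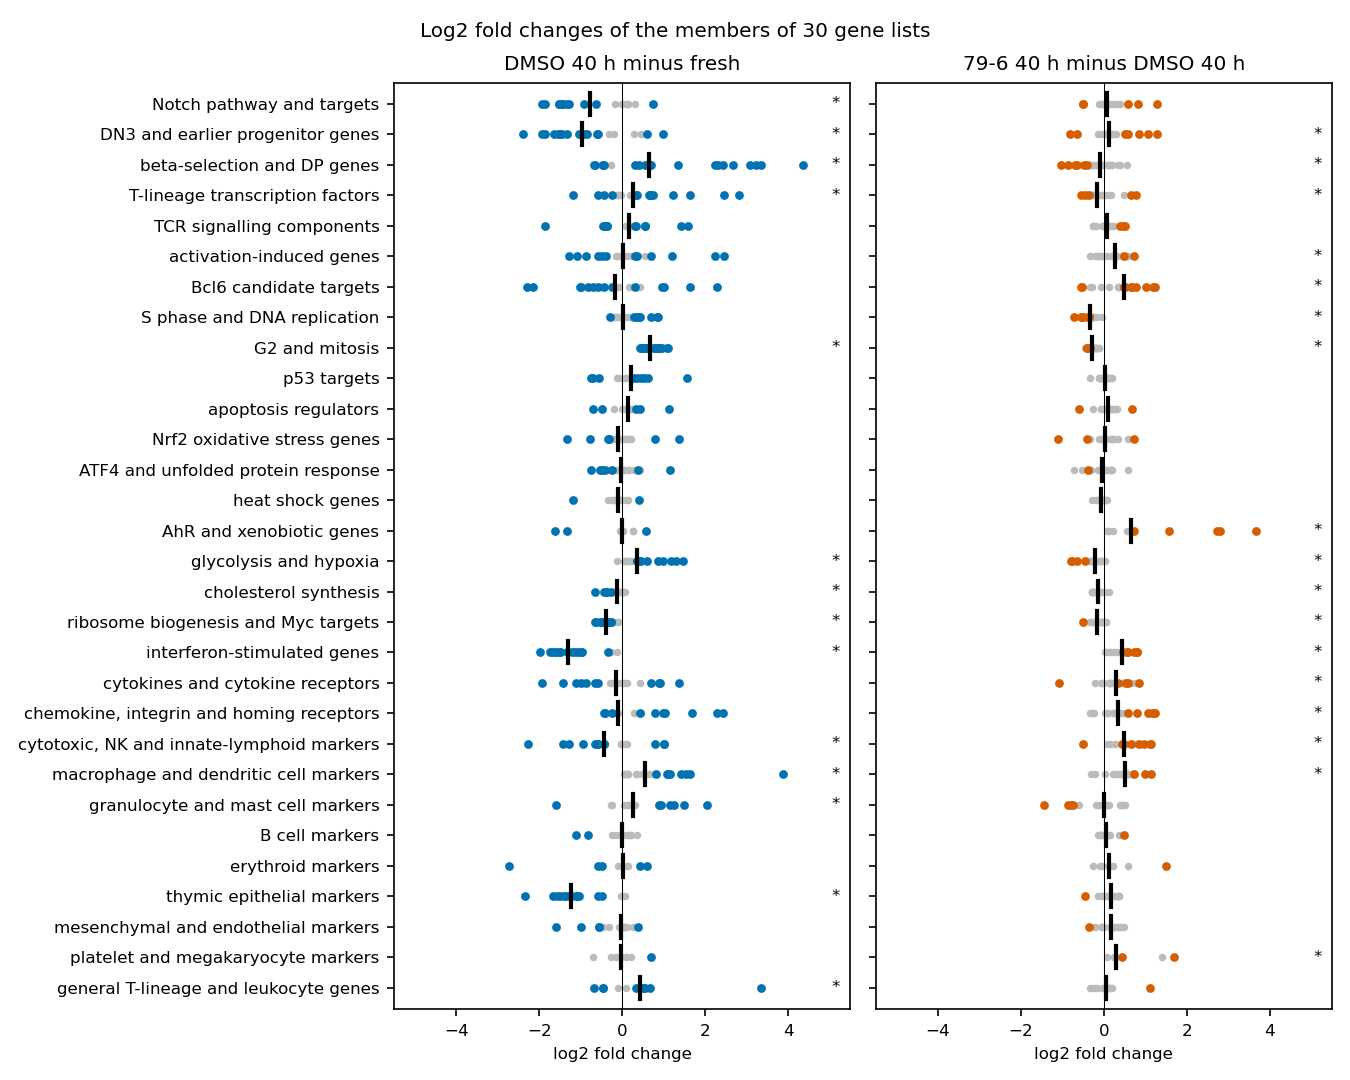
Log2 fold changes (x axis) of the members of 30 gene lists (y axis) for DMSO against fresh cells (left) and 79-6 against DMSO (right), n = 2 arrays per group. Each point is a gene, coloured if its adjusted p is under 0.05 (limma) and grey otherwise, bars are list medians and asterisks mark lists called by camera with the preset correlation. The Notch median is -0.78 on the left and 0.08 on the right.

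The second comparison, 79-6 against DMSO with both groups stimulated for 40 h, asks what the compound changed. The study is concerned with Bcl6 and Notch signalling in fetal thymocytes, and inhibition of Bcl6 itself was not measured here. Genes induced through AhR, the receptor that senses xenobiotics, rose strongly: Cyp1a1 went from 5.29 ± 0.04 to 8.95 ± 0.32 (SD, n = 2 each; 12.7-fold, adjusted p = 2.2e-04 by limma), and Cyp1b1 rose 6.98-fold and the AhR repressor gene Ahrr 6.62-fold. The DMSO levels of Cyp1a1 and Ahrr (5.57) lay near the 25th percentile of the DMSO arrays (5.24 and 5.22), and signal over background was not measured, so these are folds of intensity and not of transcript. The Notch target Dtx1 rose by 1.29 ± 0.07 (SE, adjusted p = 5.9e-04). Its DMSO level was 10.71 and its fresh level 12.23. Bcl6 transcript was lower, at 8.53 ± 0.02 against 9.08 ± 0.14 in DMSO (log2 change -0.55, adjusted p = 0.0251). That call was lost without DMSO replicate 1 (0.0713), DMSO replicate 2 (0.147), 79-6 replicate 1 (0.0613) or 79-6 replicate 2 (0.122), with a log2 change between -0.65 and -0.45.

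The largest rises with 79-6 were in the apolipoprotein L gene Apol7c (4.35 ± 0.22, SE, 20.3-fold) and the serpin gene Serpinb10 (4.12 ± 0.08, 17.4-fold). Beside Cyp1a1, Cyp1b1 and Ahrr, further large rises were in Scin (2.87), which encodes an actin-severing protein, Sidt1 (2.04) and the lipoxygenase gene Alox5 (1.80). The decoy receptor gene Il1r2 (1.79) and the cytokine gene Il10 (1.78) rose as well. Adjusted p-values of these 7 genes lay between 4.5e-06 and 0.0040 by limma. Scin had fallen from 11.11 in fresh cells to 7.87 in DMSO, and stood at 10.74 with 79-6. Pth, the parathyroid hormone gene (3.61 ± 0.50, adjusted p = 0.0146), and Chga, a neuroendocrine granule gene (1.96 ± 0.31, adjusted p = 0.0210), rose with DMSO arrays far apart, Pth at 5.44 and 7.33. The rise of Pth was 2.67 without DMSO replicate 1 and 4.55 without DMSO replicate 2, and its call was lost without 79-6 replicate 2 (0.0946). The call of Chga was lost without 79-6 replicate 1 (0.0606) or 2 (0.119). The largest falls were in Cpa3 (-1.43), Tdrd5 (-1.36), Tmem45a (-1.17), Dgkeos (-1.16), Camkv (-1.16), the cystine transporter gene Slc7a11 (-1.11), the cytokine receptor gene Il17rb (-1.07), Ano6 (-1.06), 1700048O20Rik (-1.06), Ccdc18 (-1.04), Slamf1 (-1.04) and Syt13 (-1.02), with adjusted p-values between 9.1e-04 and 0.0308. Calls were lost for Tmem45a without DMSO replicate 2 (0.0938) or 79-6 replicate 2 (0.107), for Syt13 without the same arrays (0.0811 and 0.0691), and for Slc7a11 without any of the 4 stimulated arrays (0.0848 to 0.155). Rag1 differed by -0.28 (adjusted p = 0.0759) and Thy1 by -0.16 (0.247).

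**Figure D2:**
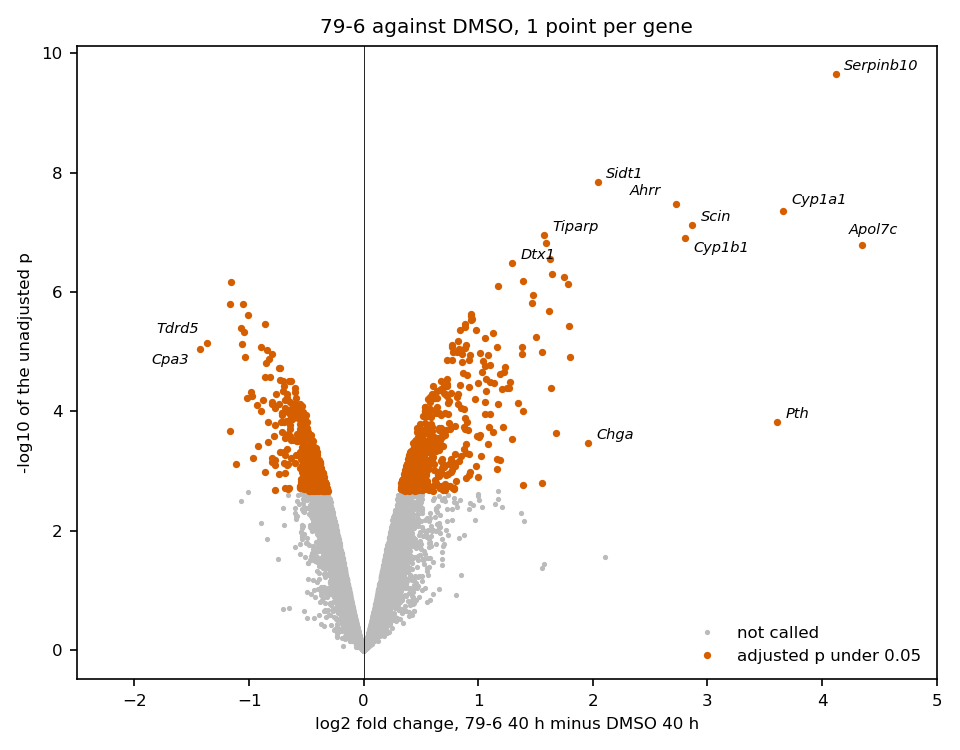
Log2 fold change of each of 19937 genes between 79-6 and DMSO (x axis) against -log10 of its unadjusted p from limma (y axis), with n = 2 arrays per group. Genes at an adjusted p under 0.05 are coloured, 475 higher and 394 lower. The AhR-induced genes Cyp1a1, Cyp1b1, Ahrr and Tiparp stand at the upper right.

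Among Notch genes the response to 79-6 was uneven. Dtx1, the glycosyltransferase gene Lfng (0.82, adjusted p = 0.0093) and Il2ra (0.58, adjusted p = 0.0114) rose and Myc (-0.51, adjusted p = 0.0215) and Igf1r (-0.49, adjusted p = 0.0309) fell, of 18 members (6 higher and 2 lower adjusted over the list alone). The classical targets Hes1 (0.07, adjusted p = 0.701), Ptcra (0.05), Nrarp (0.08) and Hey1 (-0.03) were not called, and neither were Notch1 (0.21) and Notch3 (0.28). The list median was 0.08 and camera did not call it (adjusted p = 0.0716 and adjusted p = 0.373 with an estimated correlation). It did so without DMSO replicate 2 or 79-6 replicate 2. Fry, which does not compare a list with other genes, called the Notch list higher (adjusted p = 0.0160). Only Dtx1 kept its call in each fit with an array left out. Lfng lost it without DMSO replicate 2 (0.0787) or 79-6 replicate 2 (0.0615), and Il2ra without DMSO replicate 1 (0.0717) or 2 (0.0931). Myc lost it without DMSO replicate 1 (0.123), DMSO replicate 2 (0.124) or 79-6 replicate 2 (0.107), and Igf1r without any array but 79-6 replicate 1 (0.0531 to 0.170).

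The stage lists were read on arrays where macrophage and NK marker lists were higher with 79-6 (medians 0.52 and 0.49). Which cells carry the changes was not resolved. Genes of the DN3 and earlier stages rose with 79-6 in 5 of 20 cases and fell in 2 (8 and 2 adjusted over the list alone). Kit (1.06) and the progenitor factor Lmo2 (0.86) rose beside Dtx1. Dntt (-0.80) and the recombinase gene Rag2 (-0.66) fell. The median was 0.12 (camera, adjusted p = 0.0036 and adjusted p = 0.373 with an estimated correlation). Beta-selection and DP genes fell in 6 of 22 cases with none higher (10 lower and 4 higher adjusted over the list alone), among them Slamf1, Aqp11 (-0.86), Cd6 (-0.69) and Cd4 (-0.48). Cd8a (0.12, adjusted p = 0.393) and Cd8b1 (-0.01) were not called. That median was -0.09 (camera, adjusted p = 0.0062 and adjusted p = 0.373 with an estimated correlation), and the list was not called on ranks (0.133). T-lineage transcription factors had 2 higher and 3 lower of 20 (3 and 6 adjusted over the list alone). Runx3, a factor of the CD8 and innate-like lineages, rose by 0.77 and Id2 by 0.65, and Satb1 (-0.46) fell with Bcl6. The median was -0.18 (camera, adjusted p = 0.0118 and adjusted p = 0.427 with an estimated correlation), a call lost without 79-6 replicate 1 (0.0581). In the general T-lineage and leukocyte list 1 of 13 changed, Cd7 (1.11; 1 higher and 1 lower adjusted over the list alone); its median was 0.05 while camera's direction was down (adjusted p = 0.984). Without DMSO replicate 1, DMSO replicate 2 or 79-6 replicate 2, the numbers called were 3, 3 and 5 in the DN3 list, 2, 1 and 2 in the DP list, 1, 1 and 1 among the factors and 0, 0 and 0 in the general list. No factor was called lower without 79-6 replicate 1. Kit, Lmo2, Slamf1 and Runx3 kept their calls in each of the 6 fits. Aqp11 lost its call without DMSO replicate 2 (0.0581), Dntt without DMSO replicate 1 (0.0686) or 2 (0.0869), Cd6, Id2 and Cd7 without those arrays or 79-6 replicate 2 (0.0516 to 0.124). Rag2 and Satb1 lost theirs without any stimulated array (0.0503 to 0.225) and Cd4 without any of the 6 (up to 0.193).

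Candidate Bcl6 targets rose in 9 of 21 cases and fell in 2, Bcl6 and the checkpoint kinase gene Chek1 (-0.54, with 14 and 4 adjusted over the list alone). S1pr1 (1.22), the cytokine signalling inhibitor Socs2 (1.17), Klf2 (1.01), Runx3, the survival gene Bcl2 (0.68) and Id2 were among the rises. The median was 0.48 (camera, adjusted p = 2.2e-05 and adjusted p = 0.373 with an estimated correlation). Of these, Bcl2, Id2, Runx3 and others also stand in further lists: 11 members of this list do. Macrophage and NK marker lists, the latter with Id2, were also higher on these arrays (medians 0.52 and 0.49), so which cells carry the rises was not resolved. Activation-induced genes rose in 2 of 22 cases, Fosb (0.73) and Irf4 (0.48), with none lower (9 higher and 1 lower adjusted over the list alone). The median was 0.26 (camera, adjusted p = 0.0085 and adjusted p = 0.496 with an estimated correlation), a call lost without DMSO replicate 1 (0.0780). T cell receptor signalling components had 3 higher of 17, Ptpn6 (0.50), Malt1 (0.46) and Prkcq (0.39), and were not called as a list (3 higher and 1 lower adjusted over the list alone, median 0.07, adjusted p = 0.226). Without DMSO replicate 1, DMSO replicate 2 or 79-6 replicate 2, 4, 3 and 4 Bcl6 candidates were called higher and none lower, and no activation gene or T cell receptor component was called. Without 79-6 replicate 1, 1 of each was called, and without either fresh array 1 T cell receptor component. Socs2 and Klf2 kept their calls in each of the 6 fits. S1pr1 lost its call without DMSO replicate 1 (0.0567) or 2 (0.0607), Bcl2 without DMSO replicate 2 (0.0896) or 79-6 replicate 2 (0.110), and Id2, Chek1, Fosb, Irf4, Ptpn6, Malt1 and Prkcq without either DMSO array or 79-6 replicate 2 (0.0761 to 0.220). Fosb, Malt1 and Prkcq also lost it without 79-6 replicate 1 (0.0561 to 0.0770), and Malt1 and Prkcq without either fresh array (0.0536 and 0.0542).

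Cell cycle lists were called lower with 79-6 at the preset correlation, on arrays where the macrophage median was higher by 0.52. Of 23 S phase and replication genes 10 fell with none higher (21 lower adjusted over the list alone), including the replication factor Gins1 (-0.71), the cyclin Ccne2 (-0.54), Cdc6 (-0.53) and the polymerase gene Pola1 (-0.51). The median was -0.33 (camera, adjusted p = 1.4e-16 and adjusted p = 0.266 with an estimated correlation). Of 21 G2 and mitosis genes 3 fell, Cenpe (-0.40), Ttk (-0.40) and Kif20a (-0.33), and none rose (16 lower adjusted over the list alone). Their median was -0.29 (camera, adjusted p = 4.0e-12 and adjusted p = 0.373 with an estimated correlation). Glycolysis and hypoxia genes fell in 4 of 19 cases with none higher (8 lower adjusted over the list alone), with the angiogenic factor Vegfa (-0.78), Egln3 (-0.77) and Bnip3 (-0.65) furthest down. The median was -0.20 (camera, adjusted p = 4.3e-07 and adjusted p = 0.427 with an estimated correlation). In the ribosome biogenesis list Myc alone of 20 was called, lower (2 lower adjusted over the list alone, median -0.16, camera adjusted p = 1.2e-04 and adjusted p = 0.427 with an estimated correlation). Limma called no cholesterol synthesis gene of 16 (0 adjusted over the list alone, 5 at an unadjusted p under 0.05, median -0.13). Camera called the list (adjusted p = 0.0029 and adjusted p = 0.529 with an estimated correlation) except without 79-6 replicate 2 (0.194). No S phase, mitosis or ribosome gene was called without DMSO replicate 1, DMSO replicate 2 or 79-6 replicate 2, 5 S phase genes and 1 mitotic gene without 79-6 replicate 1, and 3 S phase genes and no mitotic gene without either fresh array. The glycolysis list had 3, 0 and 0 called without the first 3 arrays, 1 without 79-6 replicate 1 and 2 without either fresh array. The highest adjusted p in these fits was 0.0905 for Gins1, 0.172 for Ccne2, 0.110 for Cdc6, 0.191 for Pola1, 0.107 for Vegfa, 0.0678 for Egln3 and 0.166 for Bnip3, with no change of direction.

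Homing, innate-like lymphocyte and macrophage lists were called higher with 79-6 by camera at the preset correlation, though most of their members were not called. Of the lists given here, fry called homing (adjusted p = 0.0470) and interferon genes (0.0442) higher. It did not call the NK (0.0544), cytokine (0.157) or macrophage list (0.207). In the homing list 6 of 19 rose with none lower (11 higher and 3 lower adjusted over the list alone). Among them were S1pr1, the chemokine receptor Cxcr6 (1.07), and Itgae (1.17) and Itgb7 (1.20), which encode the 2 chains of an integrin of intraepithelial lymphocytes. The median was 0.34 (camera, adjusted p = 5.9e-05 and adjusted p = 0.373 with an estimated correlation). Cytotoxic, NK and innate-lymphoid markers rose in 7 of 17 cases, among them the granzyme gene Gzmb (1.13), Nkg7 (1.12) and Klrd1 (0.97), and Gzma fell by 0.51 (12 higher and 1 lower adjusted over the list alone). Their median was 0.49 (camera, adjusted p = 4.5e-08 and adjusted p = 0.373 with an estimated correlation). Interferon-stimulated genes rose in 6 of 17 cases with none lower (13 adjusted over the list alone), among them Ifit3 (0.80), Cxcl10 (0.79), Rsad2 (0.73) and Irf7 (0.59). The median was 0.43 (camera, adjusted p = 1.7e-08 and adjusted p = 0.373 with an estimated correlation). Cytokines and receptors had 4 of 21 higher, including the interleukin receptor chains Il2rb (0.85) and Il2ra, and 1 lower, Il17rb (9 and 2 adjusted over the list alone). Their median was 0.30 (camera, adjusted p = 0.0016 and adjusted p = 0.427 with an estimated correlation). Macrophage and dendritic cell markers rose in 3 of 20 cases, Itgax (1.14), C1qa (0.98) and H2-Aa (0.72), with none lower (8 adjusted over the list alone). Their median was 0.52 (camera, adjusted p = 6.6e-05 and adjusted p = 0.485 with an estimated correlation), while Lyz2 differed by 0.26 (adjusted p = 0.564). Relative to the fresh mean, the macrophage median was 0.51 and 0.60 on the DMSO arrays and 1.19 on both 79-6 arrays. Without DMSO replicate 1, DMSO replicate 2 or 79-6 replicate 2, the rises called were 1, 1 and 2 for homing, 2, 1 and 1 for NK, 0, 0 and 0 for interferon, 0, 0 and 1 for cytokine and 0, 2 and 0 for macrophage genes. Without 79-6 replicate 1 they were 4 for NK, 1 for cytokine and 1 for macrophage genes. Without either fresh array 8 macrophage markers were called. Itgae, Nkg7 and Il17rb kept their calls in each of the 6 fits. Itgb7, Cxcr6, Gzmb, Klrd1, Gzma, Ifit3, Cxcl10, Rsad2, Irf7, Il2rb, Itgax, C1qa and H2-Aa each lost theirs in at least 3 of the 4 fits without a stimulated array, with adjusted p-values up to 0.207.

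In the AhR and xenobiotic list 5 of 10 members rose with none lower (6 adjusted over the list alone). They were Cyp1a1, Cyp1b1, Ahrr, Tiparp (1.57, adjusted p = 3.5e-04) and the quinone reductase gene Nqo1 (0.74, adjusted p = 0.0378); Ahr itself differed by 0.09 (adjusted p = 0.668). The median was 0.65 (camera, adjusted p = 1.1e-08 and adjusted p = 0.266 with an estimated correlation). In the main test camera did not call the other stress lists. Fry called 1 of them, the ATF4 and unfolded protein response list, lower (adjusted p = 0.0340). Limma called none of 18 p53 targets (0 adjusted over the list alone, 1 at an unadjusted p under 0.05), with a median of 0.03 and camera's direction down (adjusted p = 0.930). It called none of 13 heat shock genes either (0 adjusted over the list alone, 3 at an unadjusted p under 0.05, median -0.06). Camera did not call them (adjusted p = 0.0941) except with the mean of a gene's probe sets (0.0198). Nrf2 genes had Nqo1 higher and Slc7a11 and Gsta4 (-0.41) lower of 19 (3 and 3 adjusted over the list alone, median 0.03, adjusted p = 0.528). ATF4 and unfolded protein response genes had 1 lower of 21, the serine synthesis gene Phgdh (-0.38, with 5 lower adjusted over the list alone, median -0.05, adjusted p = 0.248). Of 15 apoptosis regulators Bcl2 rose and Bcl2l1 fell by 0.59 (2 and 2 adjusted over the list alone, median 0.10, adjusted p = 0.248). Cyp1a1, Cyp1b1, Ahrr and Tiparp kept their calls in each of the 6 fits, whereas Nqo1 lost it in all but the fit without DMSO replicate 2 (0.0561 to 0.120). Gsta4 and Phgdh lost theirs in each of the 6 fits (up to 0.199), while 2 other ATF4 list genes were called lower without 79-6 replicate 1. Calls were also lost for Slc7a11 without any stimulated array, Bcl2l1 without either DMSO array or 79-6 replicate 2 (up to 0.0938) and Bcl2 without DMSO replicate 2 or 79-6 replicate 2 (up to 0.110).

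Among other marker lists, platelet markers rose with 79-6 in 2 of 7 cases, Pf4 (1.68) and Itgb3 (0.43; 5 higher adjusted over the list alone, median 0.29, camera adjusted p = 4.0e-04 and adjusted p = 0.373 with an estimated correlation). Neither was called without DMSO replicate 1, DMSO replicate 2 or 79-6 replicate 2 (0.0709 to 0.170), and Itgb3 was not called without any other array either (0.0523 to 0.0602). Granulocyte and mast cell markers fell in 4 of 15 cases, Cpa3, Mpo (-0.86), Prtn3 (-0.80) and Ctsg (-0.74), with none higher (5 lower and 1 higher adjusted over the list alone). Here the median was 0.01, the mean -0.18 and camera's direction down (adjusted p = 0.0941), with a call without DMSO replicate 2 (0.0389) or 79-6 replicate 2 (0.0111). Only Cpa3 kept its call in each of the 6 fits; Mpo and Prtn3 lost it without any stimulated array and Ctsg without DMSO replicate 1 or 79-6 replicate 2, with adjusted p-values up to 0.156. These falls in listed granulocyte and mast cell markers stood beside the rises in macrophage and lymphoid markers. Cpa3 was at 11.50 in fresh Thy1.2+ cells, 9.90 in DMSO and 8.47 with 79-6, and which cells carry it was not tested. Cd79b (0.50) was the member called higher of 12 B cell markers (median 0.05, adjusted p = 0.566), and the carbonic anhydrase gene Car2 (1.51) of 9 erythroid markers (median 0.14, adjusted p = 0.226). Cldn4 (-0.46) was called lower of 16 thymic epithelial markers (median 0.17, adjusted p = 0.188; 2.1e-04 without DMSO replicate 2) and Pdgfrb (-0.37) of 15 mesenchymal and endothelial markers (median 0.16, adjusted p = 0.226; 0.0283 without DMSO replicate 2). Adjusted over the list alone the higher and lower counts were 1 and 0, 1 and 1, 1 and 1, and 0 and 1 for these 4 lists. Car2 kept its call in each of the 6 fits, Cd79b lost it without either DMSO array or 79-6 replicate 2 (up to 0.126), and Cldn4 and Pdgfrb lost it in all 6 (up to 0.222). Called higher were 1 thymic epithelial marker without DMSO replicate 2 and 2 granulocyte markers without 79-6 replicate 1.

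Limma called 869 of 19937 genes between 79-6 and DMSO, 475 higher and 394 lower, of which 81 differed at least 2-fold, 68 of them higher. Lower genes outnumbered higher ones with trend and robust settings (811 higher, 912 lower) and without the dimmest genes (587 and 592). When every probe set was tested 88 probe sets were called, 60 higher and 28 lower. The count was 113 without DMSO replicate 1, 93 without DMSO replicate 2 and 127 without 79-6 replicate 2, against 661 without 79-6 replicate 1 and 631 without either fresh array. With the macrophage marker covariate it was 21, of which 19 were shared with the 869. Of 110 list members and rule-named genes called here, 29 kept the call in each of the 6 fits and none changed direction. Of 102 genes named for this comparison, called or not, 62 lost their call when every probe set was tested and 78 with the macrophage marker covariate. Camera called 17 of 30 lists, 10 up and 7 down, and fry called 10, with 8 called by both. With an estimated correlation camera called 0, where 3 had an unadjusted p under 0.05 and the lowest adjusted p was 0.266.

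Most genes called from fresh to DMSO were not called with 79-6, and those that were went both ways. Of the 869 genes called with 79-6, 499 were also called from fresh to DMSO, 293 in opposite directions and 206 in the same direction, and 370 were not called from fresh to DMSO. Opposite and same directions numbered 196 and 113 without fresh replicate 1, 162 and 164 without fresh replicate 2, 42 and 29 without DMSO replicate 1, 38 and 23 without DMSO replicate 2, 217 and 122 without 79-6 replicate 1, and 47 and 37 without 79-6 replicate 2. Dtx1, Kit and Il2ra fell from fresh to DMSO and were higher with 79-6. Cd4 and Bcl6 rose from fresh to DMSO and were lower with 79-6, and S1pr1, Klf2 and Itgb7 rose in both. Independent changes would put 50.7 genes among those lower from fresh to DMSO and higher with 79-6, where 147 were found. They would put 35.0 in the reverse pair (146 found), 42.2 among those higher in both (127 found) and 42.1 among those lower in both (79 found). Both comparisons use the DMSO arrays, which pulls opposite changes together. Across genes the log2 changes correlated at -0.075 (Spearman -0.098). Their covariance was -0.00626, against -0.00510 simulated for groups that do not differ. The simulated correlation, a mean of -0.500, follows from the shared arrays where no gene changes, so -0.075 cannot be set against it. The correlation was -0.124 without fresh replicate 1, -0.0253 without fresh replicate 2, -0.137 without DMSO replicate 1 and -0.143 without DMSO replicate 2. With 1 DMSO array used for each comparison it was 0.0019, and genes are not independent replicates.

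**Figure D3:**
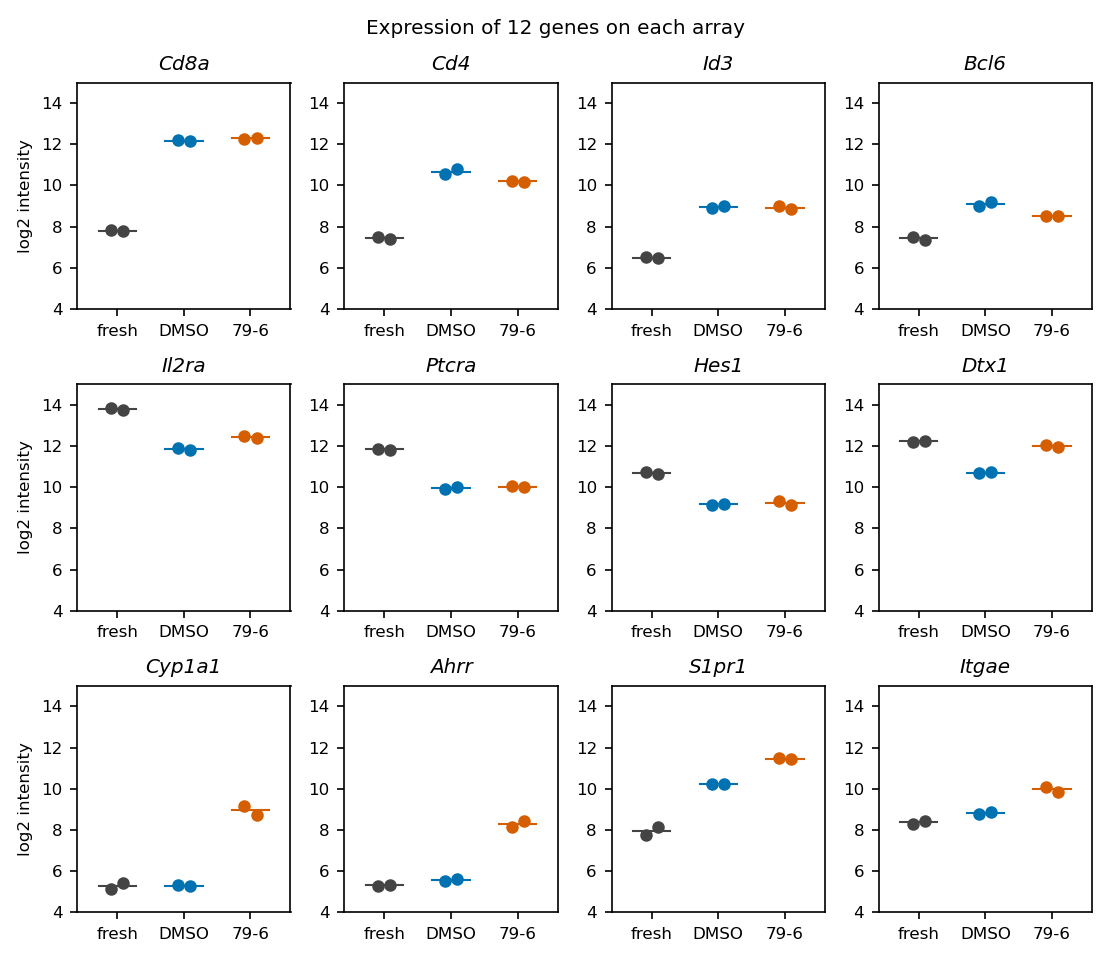
Log2 intensity (y axis) of 12 genes on each array, by group (x axis): fresh cells at 0 h, DMSO at 40 h and 79-6 at 40 h. Points are arrays (n = 2 per group) and lines are group means. Cyp1a1 and Ahrr are raised on the 79-6 arrays, Dtx1 is near its fresh level of 12.23 there, and Hes1 and Ptcra are at their DMSO levels.

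The third comparison, 79-6 at 40 h against fresh cells, asks which changes of the cultured cells were present when the inhibitor was. Cd8a was 22.3-fold higher than in fresh cells (4.48 ± 0.07, SE, adjusted p = 3.8e-07 by limma), as in the DMSO group, and Fbp1 56.7-fold lower (-5.83). Bcl6 was higher by 1.09 (adjusted p = 2.3e-04). Mmp8 (5.33), Serpinb10 (4.88), Gimap3 (4.28), Lyz2 (4.13), Ifitm6 (3.81), Cyp1a1 (3.65), Gpr141 (3.60), Ly6a2 (3.60), S1pr1 (3.50), Cd2 (3.45) and Pth (3.44) made up the other large rises. Khdc1a (-4.50), Vwce (-3.36), Myl10 (-3.15), Cdh23 (-3.10), Cpa3 (-3.04), Capn5 (-2.99), Uaca (-2.94), Mpzl2 (-2.89), B4galnt2 (-2.81), Gm10384 (-2.81) and Stc1 (-2.79) made up the other large falls. Rag1 signal was lower by a log2 change of -0.63 (adjusted p = 8.9e-04) and Thy1 higher by 0.26 (0.0300), a call that Thy1 lost without either fresh array or either 79-6 array (up to 0.152).

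Notch genes were mostly below their fresh level with 79-6, with 10 of 18 lower and 2 higher (11 and 2 adjusted over the list alone, median -0.61, camera adjusted p = 2.3e-04 and adjusted p = 0.340 with an estimated correlation). Ptcra (-1.81), Hes1 (-1.45) and Il2ra (-1.37) were lower and Lfng (1.11) higher, and Dtx1 was not called (-0.23, adjusted p = 0.0597). Of the 10 lower members 9 were also lower in DMSO than in fresh cells, and Igf1r was lower in the 79-6 group only. DN3 genes were lower in 14 of 20 cases and higher in 3 (15 and 3 adjusted over the list alone, median -0.77, adjusted p = 3.2e-07 and adjusted p = 0.299 with an estimated correlation). Beta-selection and DP genes were higher in 13 of 22 cases and lower in 7 (13 and 7 adjusted over the list alone, median 0.62, adjusted p = 0.0039 and adjusted p = 0.357 with an estimated correlation, and 0.0709 on ranks). S phase genes were lower (12 of 23, 2 higher, with 13 and 2 adjusted over the list alone, median -0.30, adjusted p = 4.2e-04 and adjusted p = 0.372 with an estimated correlation). Mitotic genes were higher (17 of 21, with 19 adjusted over the list alone, median 0.48, adjusted p = 2.4e-08 and adjusted p = 0.372 with an estimated correlation). AhR genes were higher in 5 of 10 cases and lower in 2 (5 and 2 adjusted over the list alone, median 0.50, adjusted p = 0.0125 and adjusted p = 0.357 with an estimated correlation, and 0.0649 on ranks). Macrophage markers were higher in 17 of 20 cases (17 adjusted over the list alone, median 1.14, adjusted p = 1.0e-07 and adjusted p = 0.482 with an estimated correlation). Thymic epithelial markers were lower in 12 of 16 cases with 1 higher (13 and 1 adjusted over the list alone, median -1.14, adjusted p = 1.7e-07 and adjusted p = 0.357 with an estimated correlation). None of the latter was called higher without fresh replicate 1, 1 S phase gene was higher without fresh replicate 2, and 1 AhR gene lower without either fresh array or 79-6 replicate 2.

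Interferon-stimulated genes were lower with 79-6 than in fresh cells in 14 of 17 cases (median -0.91, adjusted p = 3.3e-10 and adjusted p = 0.357 with an estimated correlation). Ribosome biogenesis genes were lower in 17 of 20 (median -0.48, adjusted p = 1.7e-10 and adjusted p = 0.357 with an estimated correlation) and cholesterol synthesis genes in 7 of 16 (median -0.29, adjusted p = 1.8e-04 and adjusted p = 0.482 with an estimated correlation). Cholesterol genes called lower numbered 11 without 79-6 replicate 1 and 4 without fresh replicate 1. Homing receptors were higher in 10 of 19 cases and lower in 3 (median 0.56, adjusted p = 0.0039 and adjusted p = 0.482 with an estimated correlation). Heat shock genes were lower (3 of 13, 1 higher, median -0.14, adjusted p = 0.0286 and adjusted p = 0.372 with an estimated correlation), a call lost without 79-6 replicate 2 (0.0767). Apoptosis regulators were higher (5 of 15, 1 lower, median 0.22, adjusted p = 0.0425 and adjusted p = 0.357 with an estimated correlation), a call lost without fresh replicate 1 or either 79-6 array (0.0528 to 0.0679). Platelet markers were higher (4 of 7, median 0.36, adjusted p = 0.0435 and adjusted p = 0.482 with an estimated correlation), a call lost without fresh replicate 1 (0.0581) or 79-6 replicate 2 (0.0844), and on ranks (0.0649). Platelet markers called higher numbered 2 without fresh replicate 1 and 1 without 79-6 replicate 2, apoptosis regulators 3 without fresh replicate 2, and heat shock genes called lower 2 without either fresh array or 79-6 replicate 2. Adjusted over the list alone the lower counts were 14, 20 and 9 for interferon, ribosome and cholesterol genes. The single rise among heat shock genes and the single fall among apoptosis regulators were not called with any array left out. The higher and lower counts adjusted over the list alone were 10 and 3 for homing, 1 and 4 for heat shock, 7 and 1 for apoptosis and 4 and 0 for platelet genes.

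The other 15 lists were not called against fresh cells, with the lowest adjusted p at 0.0638 for T-lineage transcription factors, and their medians lay between -0.05 for Nrf2 genes and 0.29 for T cell receptor signalling components. Without fresh replicate 2, lists of T-lineage transcription factors (0.0419), activation-induced genes (0.00447), glycolysis genes (0.0338) and NK markers (0.0310) were called. Median and mean differed in sign for B cell markers (0.08 and -0.04), erythroid markers (0.18 and -0.04) and mesenchymal markers (0.10 and -0.11, with camera's direction down). Limma called 5174 genes, 2401 higher and 2773 lower, with 682 at least 2-fold apart. The larger direction turned with quantile normalisation (2825 higher, 2591 lower), with arrays set to 1 median (2978 and 2504) and without 79-6 replicate 1 (2542 and 2526). The number called was 3081 without fresh replicate 1, 3321 without fresh replicate 2 and 147 with the macrophage marker covariate. Camera called 15 of 30 lists, 7 up and 8 down, and fry called 21, with 15 called by both. With an estimated correlation camera called 0, where 2 had an unadjusted p under 0.05 and the lowest adjusted p was 0.299.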

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

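The tests of explanations in this part were chosen after the results they weigh had been seen. The camera, fry, leave-one-out and every-probe-set results repeated here were planned. Outside the named genes, 17 of 13120 probe sets without a single gene symbol were called between 79-6 and DMSO arrays, 7 higher and 10 lower, with changes between -1.60 and 1.53; they are given because the 3 comparisons tested probe sets with a single gene symbol, and these entered only when every probe set was tested.

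The AhR pattern is the rise of Cyp1a1, Cyp1b1, Ahrr, Tiparp and Nqo1 with 79-6. More macrophage RNA in the 79-6 arrays is argued against by the step from fresh to DMSO, for macrophages not exposed to 79-6. There the macrophage median rose by 0.557 (0.516 with 79-6). The median of these 5 genes changed by -0.0122 (-1.34 to 0.58), against 2.73 with 79-6. That step is imprecise: the macrophage medians of the fresh arrays were -0.344 and 0.344, and the 5 genes were called against the same DMSO arrays. It holds no 79-6, so induction of these genes by the compound within macrophages was not tested. A general stress response is argued against by 69 members of the Nrf2, ATF4, heat shock and p53 lists that are not in the AhR list, whose median change was -0.0179 (SD 0.25), with 0 called higher and 3 lower. The pattern may therefore reflect AhR activity itself, as a hypothesis; whether the compound acts on AhR directly, through Bcl6 or in which cells stays open, because no array holds 79-6 without its target or without anti-CD3.

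Macrophage and innate-lymphoid lists were called higher with 79-6 by camera at the preset correlation, with 3 of 20 and 7 of 17 members called. They were not called with an estimated correlation (adjusted p = 0.485 and 0.373) or by fry (adjusted p = 0.207 and 0.0544). Fewer members of each stayed called without either DMSO array or 79-6 replicate 2. A lower share of T-lineage cells would raise every other cell type's markers alike. The gap between the macrophage and the granulocyte and mast cell medians was 0.204 and 0.364 on the DMSO arrays. On the 79-6 arrays it was 1.05 and 0.937, a difference of 0.709 against a pooled SD of 0.0976 over both groups. That SD leaves out the fresh arrays, where macrophage medians were -0.344 and 0.344 and granulocyte medians -0.058 and 0.058. The gap thus also differed between fresh replicates, so its shift does not decide against a lower T-lineage share. With the macrophage median as a covariate all 869 changes called kept their direction and a median of 0.906 of their size, but 21 were called, as the median SE rose from 0.0837 to 0.142. Whether macrophage RNA carries part of the response cannot be told apart from the treatment here, because the covariate's slope rests mainly on the difference between the fresh arrays. A change in the number or state of macrophages and innate lymphocytes under 79-6 stays open, and Thy1.2 purification would remove most macrophages but not Thy1-positive innate cells.

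Pth and Chga were higher on both 79-6 arrays (9.99 for Pth on 79-6 replicate 2) and differed between the DMSO arrays (5.44 and 7.33). Parathyroid tissue carried with some thymi is one candidate source, although how much such tissue remained after Thy1.2 purification was not measured. Casr, another parathyroid gene, differed by 0.301 (95% interval 0.065 to 0.538, adjusted p = 0.151 by limma), which neither meets nor excludes that source. A larger share of thymic epithelium as a whole is argued against by the 16 epithelial markers, whose median change was 0.173 (SD 0.227). Chga changed by 1.96 and Pth by 3.61. Relative to fresh, the epithelial median was -1.38 and -1.02 on the DMSO arrays, lower on replicate 1 like Pth. On the 79-6 arrays it was -1.18 and -1.17. A subset of epithelial cells was not tested. The labels give no dissection or litter per array, so whether the source lies in the cultured thymi or in the treatment stays open.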

How the results depend on the processing

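The macrophage covariate was the alternative chosen after the results had been seen; the others were planned. The counts of genes kept within 1.5 times their value under a fit of the compared groups alone, the omission of dim genes, both rescalings and the mean of a gene's probe sets, and the counts of lists under the omission of dim genes, the mean of probe sets and ranks. Without dim genes the calls of the cholesterol (0.0505) and general T-lineage lists (0.0576) ended and that of p53 targets began (0.0468) for DMSO against fresh, and the calls of heat shock genes (0.0787) and platelet markers (0.0787) ended and that of activation-induced genes began (0.0487) for 79-6 against fresh. The larger direction turned with arrays set to 1 median for DMSO against fresh (2155 higher, 1822 lower), and with either rescaling for 79-6 against fresh (2825 and 2591, 2978 and 2504). With the replicate block, genes called numbered 3667 for DMSO against fresh, 774 for 79-6 against DMSO and 4852 for 79-6 against fresh, and lists 14, 17 and 15. With trend and robust settings 79-6 against DMSO gave 1723 genes, and with every probe set tested 88 probe sets, for which the cause was not tested. With a fold of at least 2 the counts were 519, 81 and 682, fewer by construction. With the macrophage covariate they were 1434, 21 and 147. A lost degree of freedom does not account for this drop, since the replicate block spent a degree of freedom too. The covariate itself differed between groups, at -0.34 and 0.34 on fresh, 0.51 and 0.60 on DMSO and 1.19 on both 79-6 arrays. For the 869 genes called with 79-6 the median SE rose from 0.0837 to 0.142. Leaving out each array in turn gave 2286 to 4070, 93 to 661 and 3081 to 5068 genes, with fewer residual degrees of freedom and 1 array left in a group, 13 to 15, 16 to 21 and 12 to 19 lists, and a correlation between both responses of -0.143 to -0.0253. That correlation turned to 0.00193 when each comparison had a DMSO array of its own, which removes the shared noise by construction. With the correlation estimated per list camera called 0 lists in each comparison, where the lowest adjusted p-values were 0.196, 0.266 and 0.299. For DMSO against fresh, the Notch and DN3 lists had estimated correlations of -0.036 and 0.00094, below the preset 0.01. Correlation between genes therefore does not account for the loss of their calls. For the Notch list camera's unadjusted p went from 4.1e-06 to 0.0155. The estimated variant rests on the 3 residual degrees of freedom, so its count of 0 does not weigh correlation between genes alone. Changes of sign of values that no fit called were not counted as reversals. Scaling moved the median change of all genes by less than 0.1, and signal over background was not measured, so dim genes carry the least precision.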

Other observations

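The genes in this part were chosen after their values had been seen, and no explanation was tested for them. Members of the Gimap family, GTPases of lymphocyte survival encoded side by side, were higher with 79-6 than with DMSO: 5 of 8 measured members were called higher and 0 lower, Gimap3 (1.39), Gimap4 (0.68), Gimap8 (0.55), Gimap6 (0.44) and Gimap5 (0.41), with a median of 0.43 and the same sign under both rescalings. They had also risen from fresh to DMSO, 7 of 8 with a median of 1.22. Their probe sets can read one another's transcripts. The microRNA genes Mir181a-1 (-1.01, adjusted p = 0.0020) and Mir181b-1 (-0.93, adjusted p = 0.0106), which raise the sensitivity of T cell receptor signalling in thymocytes, were lower with 79-6, and so was the inhibitory receptor gene Pdcd1 (-0.86). The related Mir181a-2 (-0.26, adjusted p = 0.185) and Mir181b-2 (-0.20, adjusted p = 0.258) were not called. Array probes for these loci read precursors, not mature microRNA.

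Further genes higher with 79-6 included the receptor genes Cd160 (1.59) and Jaml (1.65) of intraepithelial and innate-like lymphocytes, the kinase gene Stk39 (1.74), the phosphatase gene Acpp (1.62), Stfa3 (1.47), Plet1 (1.38), Asb2 (1.38) and the transcription factor gene Ikzf2 (0.46). Dgke (-0.98) was lower beside Dgkeos (-1.16), its neighbour on the opposite strand. The chemokine gene Xcl1 differed by 0.77 and was not called (adjusted p = 0.0850).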
